A study of Arabidopsis thaliana with 12 samples.

How the data were processed

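The series holds 12 stranded RNA-seq libraries of 7-day-old Arabidopsis thaliana seedlings of an inducible RNA interference line against RRP41. Poly(A)+ libraries (TruSeq Stranded mRNA) and ribo-minus libraries (TruSeq Stranded Total RNA with plant Ribo-Zero) were made from the same total RNA, with 3 biological replicates per group. Groups and replicate numbers were taken from the labels.

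Per the labels, the authors handled reads with CASAVA 1.8.2, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff on TAIR10. How the values per PE were made is not stated. The deposited values are a signal per window of 3000 bp and strand, in whole numbers. Their lowest values stood in simple ratios to the smallest one in 71.4% to 97.6% of cases. Of all whole numbers in the same range, 6.57% to 58.5% would do so, less than was found in each library. Such ratios are what a mean of scaled coverage over covered intervals gives, and not what read counts give. This reading of the signal was inferred from the values. Each library appears scaled by its own depth to a common, unstated total. The smallest value above 0 (107 to 1005) then stands for a coverage of about 1 read, from 1 read or several that do not overlap. It shows each library's detection limit. Under this reading, totals and shares of the signal are not amounts of RNA. Strand order followed the order named for the forward and reverse columns and was checked against windows with genes on 1 strand. In ribo-minus uninduced replicate 1 both strand columns were the same in 100% of windows.

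PEs were placed on TAIR10 with the RefSeq annotation of the same nuclear assembly (coordinates counted from 1). The host of a PE is the gene at the window's midpoint. The opposite strand was defined in the 1124 windows with annotated genes on 1 strand only. Midpoint classes were compared with 1000 sets of random positions drawn per chromosome. Neighbouring called windows that overlap on a strand were joined into loci for counting.

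Comparisons used R 4.3.3 with limma 3.58.1 (lmFit, eBayes with trend) on log2(value + 1) of the deposited values without rescaling. A tested strand was above 0 in at least 3 of the libraries fitted, and 3838 strands of windows were available. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Knockdown was fitted within each fraction (6 libraries). The fraction contrasts and the interaction were fitted on all 12 libraries with 4 group means. Numbers of PEs with signal (value of 1 or more), on any strand and on both strands, and the opposite-strand share were compared by two-sided exact permutation tests of group means, and shares of calls by Fisher's exact test. For 3 against 3 libraries the smallest exact p is 0.1 and for 2 against 3 it is 0.2. Sets were tested with camera (preset correlation 0.01, then estimated) and fry. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

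Comparisons, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule takes, among strands past the threshold with non-overlapping groups, the 10 largest rises and 10 largest falls per knockdown comparison and the 5 largest each way for the fractions and the interaction, or the 3 smallest p where none passed. Strands named outside the rule (snRNA and snoRNA windows, and those called in both fractions) were chosen after their values were seen, as were 9 sets by gene type on the strand. Gene lists covered the exosome, light harvesting and Rubisco, the clock, light signalling, auxin, flowering, cold and dehydration, root cell types, the stomatal lineage, phloem and the shoot meristem, with word patterns in gene descriptions for further lists. Lists with at least 3 tested strands entered the set tests, which left out ribosomal proteins, the clock and flowering.

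Alternatives were no filter, a stricter filter (mean of 5 or more), median-ratio scaling, limma without the trend, a pseudocount of 0.1, summed strands, the replicate number as a block, all 12 libraries in a knockdown fit, and each library left out. Chosen after seeing the data were a common floor (every value raised to 1005, the smallest value above 0 of the shallowest library) and the floor without the unstranded library. The stricter filter removed nothing that the absence of a filter kept, and detection minimums of 0.5 and 2 changed nothing, since values above 0 start at 107. Thinning to equal depth was not run, since read counts are not used here. The design included all libraries in every measure; the unstranded library was left out of the both-strand counts and opposite-strand shares. Values with it are given in the account of processing choices.

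The fits were tested on simulated data modelled on the mean signal and the within-group spread of the libraries. The spread was taken from strands with a mean well above the common floor and given to all strands. Changes were set only in strands with a mean above the floor. The numbers of changed strands recovered and of unchanged strands called therefore do not hold for strands near or below the floor. As designed, the simulated fits tested 3057 strands in poly(A)+ and 2601 in ribo-minus, against 3297 and 3231 in the real fits. As designed, 88 of 100 strands changed 2-fold and 96 of 100 changed 4-fold were recovered in poly(A)+, with 4 unchanged strands called. In ribo-minus 67 and 81 were recovered, with 4 unchanged strands called. With the common floor the numbers were 92, 98 and 9 in poly(A)+ and 74, 94 and 13 in ribo-minus. The ribo-minus numbers as designed hold for the simulated strands only. They do not give the power of the real ribo-minus fit, which tested more strands and included the unstranded library.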

Results

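RNA from 7-day-old Arabidopsis thaliana seedlings was read out over 1919 putative enhancers (PEs), each a window of 3000 bp, on both strands. The line carries an estradiol-inducible RNA interference construct against RRP41, a core subunit of the RNA exosome, the complex that degrades and trims RNA from the 3' end. Uninduced seedlings served as the control and induced seedlings as the knockdown. A change after knockdown thus means induced against uninduced throughout. Estradiol, induction of the construct and loss of RRP41 fall in the same libraries, so their effects cannot be told apart for any strand. From the same total RNA, poly(A)+ libraries and ribo-minus libraries (ribosomal RNA removed, RNA without a poly(A) tail kept) were made. The 4 groups, uninduced and induced poly(A)+ and uninduced and induced ribo-minus, held 3 biological replicates each, 12 libraries in all. The questions were whether the PEs are transcribed in seedlings with and without exosome activity, and whether their RNA is polyadenylated.

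Values were a deposited signal per window and strand. Total signal over all PEs lay between 55804893 and 58489785 in the poly(A)+ libraries. It lay between 18738150 and 22715708 in the uninduced and between 26531272 and 31455657 in the induced ribo-minus libraries. Read numbers are unknown, so no counting interval could be given. The smallest value above 0, which stands for a coverage of about 1 read, ran from 107 to 1005 between libraries, a 9.39-fold range of depth. In uninduced ribo-minus replicate 1 the values of both strands were the same in 100% of windows, so its strands were not separated. No window held RRP41 itself (0 of 1919), so the size of the knockdown was not measured here.

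The PEs lay most often at gene ends and between genes. On the TAIR10 assembly, 457 window midpoints (23.8%) fell in a 3' UTR, 206 (10.7%) in a 5' UTR and 812 (42.3%) outside annotated genes. The series describes the PEs as intragenic, and the study's own assignment of PEs to genes is not in the files, so the share outside genes holds for the annotation used here. Coding exons held 246 midpoints, introns 122, noncoding genes 61 and other UTR exons 15. Against 1000 sets of random positions on the same chromosomes, midpoints were 4.29 times as frequent in 3' UTRs and 2.37 times as frequent in 5' UTRs. They were less frequent than at random in coding exons (ratio 0.457), introns (0.414) and noncoding genes (0.320), and slightly more frequent outside genes (1.18). Each of these had a two-sided permutation p of 0.002, the smallest that 1000 sets can give, and the remaining class had p = 1. Since 580 windows overlap another window, their positions are not independent.

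Nearly every PE window gave RNA signal in these seedlings, with or without induction and in either RNA fraction. Genes are annotated on 1 strand of 1124 windows and on both strands of 794, so this signal includes that of annotated genes. Of 1919 PEs, 1706 had signal in all 12 libraries and 6 had none in any. Signal was found on average at 1867 ± 4.73 PEs (SD, n = 3) in uninduced and 1877 ± 17.7 (n = 3) in induced poly(A)+ libraries. In ribo-minus libraries it was found at 1806 ± 31.0 (n = 3) uninduced and 1859 ± 49.9 (n = 3) induced. Induced and uninduced libraries did not differ past the threshold (two-sided exact permutation p = 0.4 for poly(A)+ and 0.3 for ribo-minus, both 0.533 after adjustment over 4 comparisons). Nor did the fractions (exact p = 0.1 uninduced and 0.8 induced, adjusted 0.4 and 0.8), and 0.1 is the smallest p that 3 against 3 libraries allow. Above a floor of 1005, which every library could show, 1324 PEs had signal in all 12 libraries and 70 in none. With that floor the ribo-minus difference (induced minus uninduced, the same 6 libraries) turned from 53.0 to −39.7 PEs, with an exact permutation p of 0.8.

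After exosome knockdown, the largest rises of poly(A)+ signal were at snRNA genes, a snoRNA cluster, strands with no annotated gene and a few protein-coding genes, and the largest falls at protein-coding genes. In windows with genes on 1 strand only, 27 gene strands rose and 26 fell on the deposited scale, 34 and 16 with median-ratio scaling, and 42 and 61 with values raised to a common floor. The window over U2.6, a gene for the U2 RNA of the spliceosome (chromosome 3, 21002933 to 21005932, plus strand), went from 1542 ± 648 to 23176 ± 12118 (SD, n = 3), 14.6-fold. A window holding snoRNA and lncRNA genes beside AT3G17090 (chromosome 3, 5828015 to 5831014, minus strand) went from 508 ± 207 to 6349 ± 1321, a log2 change of 3.69 ± 0.35 (SE, adjusted p = 0.00345; 2.64 with values raised to a common floor). The strand opposite AT1G49245, next to ACT8 (chromosome 1, 18217270 to 18220269, minus strand), went from 524 ± 43.3 to 5808 ± 908 (log2 change 3.46 ± 0.23; 2.52 with the floor). The plus strand opposite AT3G43610, a gene of the spindle pole body Spc97/Spc98 family (chromosome 3, 15516144 to 15519143), went from 605 ± 103 to 6384 ± 913 (log2 change 3.40 ± 0.23; 2.66 with the floor). The last 2 changes had adjusted p = 0.00116 and no gene is annotated on the strand that rose. Uninduced values of these 3 windows lay below the common floor of 1005, so the size of their change depends on depth. An overlapping window covers the same U2.6 gene and gave the same values.

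Other strands were listed at 0 in all 3 uninduced poly(A)+ libraries and carried signal in all 3 induced ones. The minus strand at chromosome 5, 16721139 to 16724138, opposite the 5' UTR of AT5G41780, held 5247 ± 1524 (SD, n = 3) after induction (adjusted p = 0.00345). AT1G68875, an uncharacterized gene (chromosome 1, 25890343 to 25893342, plus strand), held 1174 ± 265 (adjusted p = 0.0253), close to the common floor. AT1G29870, of a tRNA synthetase family (chromosome 1, 10454951 to 10457950, minus strand), held 7630 ± 12377 (adjusted p = 0.0376), of which replicate 1 gave 21921 and the other two 535 and 433. Neither of these genes could be tested above the floor. Far more signal appeared on the minus strand of a stretch of chromosome 5. At 21820756 to 21823755, where no gene is annotated on that strand, induced poly(A)+ libraries held 271686 ± 222411 (range 28047 to 463837, adjusted p = 0.00116). At 21867321 to 21870320, over ENODL1 and opposite emb2737, signal went from 866 ± 314 to 272342 ± 222500 (adjusted p = 0.00785).

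Among the falls, the largest was at AT3G58550, a lipid-transfer protein gene (chromosome 3, 21646890 to 21649889, minus strand), from 33098 ± 8165 to 7895 ± 1606 (SD, n = 3; log2 change −2.06 ± 0.20 SE, adjusted p = 0.00345). ALN, the allantoinase of purine breakdown, fell from 10230 ± 1304 to 3794 ± 668 (log2 change −1.44 ± 0.17, adjusted p = 0.00562). The overlapping windows over the transporter genes ABCG42 and ABCG30 fell too (log2 change −1.55 and −1.44, adjusted p = 0.0134 and 0.0376). At AT5G17460, a glutamyl-tRNA(Gln) amidotransferase subunit gene, overlapping windows fell as well (log2 change −1.43 and −1.40, adjusted p = 0.00345 each). Further falls were at AT5G02430, a WD40-repeat gene (−1.29), and AT2G18330, an AAA-type ATPase gene next to RL4 (−1.13). WYR, an inner centromere protein gene, fell (−1.05), as did ESB1, a dirigent-like gene needed for the Casparian strip of the root (−0.98). The adjusted p of these last genes lay between 0.00345 and 0.0159, and each named strand differed without overlap between its 3 induced and 3 uninduced libraries, which chance gives for 10% of strands.

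In all, limma called 136 of 3297 tested strands in the poly(A)+ libraries, 78 up and 58 down (68 and 50 loci once overlapping windows are joined), while 714 had an unadjusted p under 0.05. With every value raised to the common floor, an alternative chosen after the data were seen, 262 of 2151 strands were called, 110 up and 152 down, and these include 75 of the 78 and all 58. The count fell to 68 without uninduced replicate 2, 69 without uninduced replicate 3, 84 without induced replicate 1 and 85 without induced replicate 2, and to 64 with the replicate number as a block, where AT1G29870, AT1G68875, ABCG42 and ABCG30 missed the threshold (adjusted p = 0.0943, 0.0881, 0.0633 and 0.114). ABCG30 also missed it without each of these 4 libraries, AT1G29870 without any of the uninduced ones, WYR without uninduced replicate 2 or 3 and ESB1 without uninduced replicate 2. When all 12 libraries shared their spread it was 17. Median-ratio scaling gave 132, 92 up and 40 down, and leaving out induced replicate 3 gave 202, 76 up and 126 down.

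Windows with an snRNA or snoRNA gene on the strand measured were also examined together in the poly(A)+ libraries. Of 15 tested, 7 rose (the overlapping U2.6 windows among them) and 1 fell, and 9 passed when adjusted over the list alone. U2.3 went from 17589 ± 5451 to 90898 ± 32637 (SD, n = 3; log2 change 2.36 ± 0.30 SE, adjusted p = 0.00742). A window with U6-26 and LBD22 went from 521 ± 237 to 4471 ± 845 (log2 change 3.17 ± 0.36, adjusted p = 0.00539; 2.14 with the floor). On chromosome 5, the window over snoRNA gene AT5G06565 and AT5G44286 (17838993 to 17841992, plus strand) went from 418 ± 91.7 to 2820 ± 710 (log2 change 2.75 ± 0.34, adjusted p = 0.00742; 1.46 with the floor). U1.7, which shares its window with AT3G05670, rose by 0.95 ± 0.17 (adjusted p = 0.0258). U2.10b/12 had a log2 change of 5.37 ± 2.48 (adjusted p = 0.265) and was not called as designed, but was with the common floor (1.79 ± 0.40, adjusted p = 0.0216). The window that fell holds AT1G68940 beside AT1G09027 (−0.68 ± 0.11, adjusted p = 0.0166). This set, chosen after the values were seen, was higher by camera (adjusted p = 0.00387; adjusted p = 0.414 with an estimated correlation) and by fry (adjusted p = 0.0185; 0.122 with the replicate block). U1, U2 and U6 RNAs come from families of near-identical genes, so signal at a copy cannot be assigned to that copy alone.

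**Figure D1:**
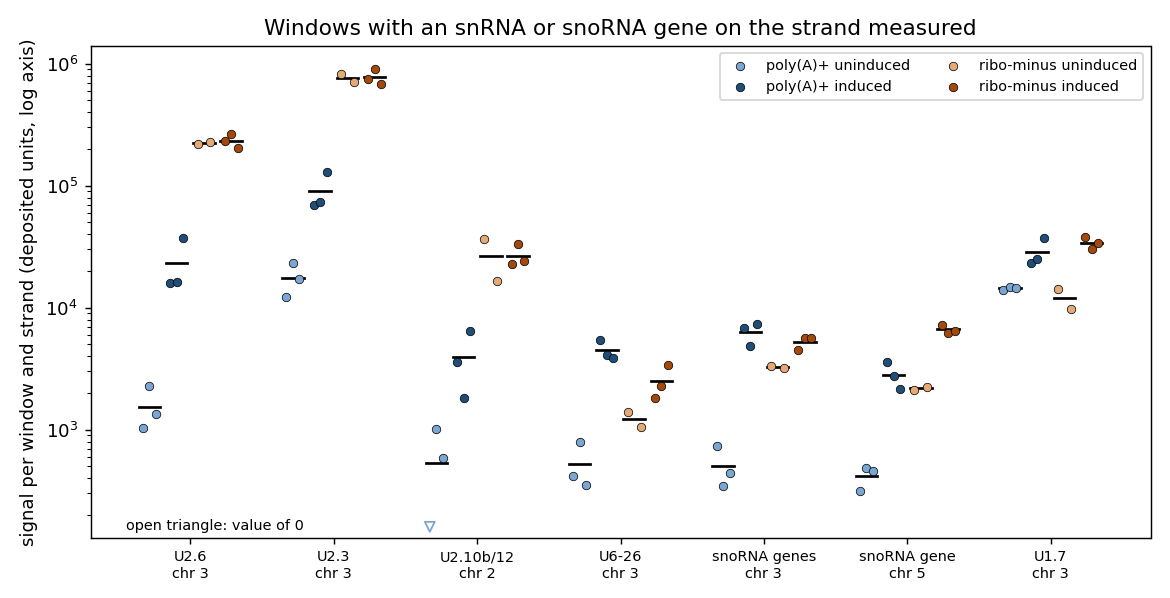
Signal (deposited units, log axis) of each library at 7 windows with an snRNA or snoRNA gene on the strand measured, by fraction and induction; points are libraries, bars are means, the open triangle is a value of 0, and ribo-minus uninduced replicate 1, whose strands were not separated, is not drawn. The windows drawn are those called up in poly(A)+ libraries as designed or with the common floor, leaving out an overlapping U2.6 window. Other windows with such genes are not drawn. Among windows so chosen, every induced poly(A)+ point lies above every uninduced one, as at U2.6 (1542 against 23176 on average). The ribo-minus points of the U2 windows overlap or lie close together.

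In the ribo-minus libraries the knockdown was marked by the same stretch of chromosome 5. Its windows at 21820756 and at 21867321, minus strand, were listed at 0 in the uninduced replicates with separated strands and reached 2774490 ± 626050 and 2774570 ± 626062 (SD, n = 3) after induction. The window between them, over AT5G53850 (21859543 to 21862542, minus strand), went from 14025 ± 3758 in all 3 uninduced replicates to 2791060 ± 626009, a log2 change of 7.65 ± 1.11 (SE, adjusted p = 0.000741). With the floor and without the unstranded library it was 7.41 ± 0.22. The 10 highest strand values of each library held between 31.4% and 41.7% of signal in induced and at most 12.05% in uninduced ribo-minus libraries. Apart from this stretch, AT5G13210, a conserved gene of unknown function, rose to 19787 ± 3386 (log2 change 2.70 ± 0.43, adjusted p = 0.00246), and the window of U1.7 and AT3G05670 rose to 34108 ± 3746 (log2 change 2.09 ± 0.42, adjusted p = 0.0381).

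These 5 strands were the only ones limma called among 3231 in the ribo-minus libraries as designed, with 0 down and 172 at an unadjusted p under 0.05. The lowest p among falls belonged to FAR1, a fatty acid reductase gene (log2 change −1.82 ± 0.45, adjusted p = 0.228), SAC8 (−1.61 ± 0.42, adjusted p = 0.298) and AT3G59930, a defensin-like gene (−1.67 ± 0.45, adjusted p = 0.337). On the common floor alone limma called 7, all up, the 5 among them, with 137 at an unadjusted p under 0.05. With the floor and without uninduced replicate 1, whose strands were not separated, it called 33 of 2070 strands, 15 up and 18 down, the 5 among them. Falls outnumbered rises without uninduced replicate 2 (13 up, 48 down), where FAR1, SAC8 and AT3G59930 were called, without uninduced replicate 3 (13 up, 46 down), where FAR1 and SAC8 were, and with no filter (11 up, 29 down). Counts were 10 without uninduced replicate 1, where AT5G13210 missed the threshold, 3 without induced replicate 1, where AT5G13210 and the U1.7 window missed it, and 12 without induced replicate 3. Median-ratio scaling moved the median change from 0.20 to 0.07 (log2) and gave 2 calls, and of the 5 strands it kept the AT5G53850 window alone.

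Several strands responded to the knockdown more in one RNA fraction than in the other, which the interaction term tested. The rise at U2.6 was larger in poly(A)+ RNA (difference of log2 changes −3.33 ± 0.58 SE, adjusted p = 0.0168). Its ribo-minus signal was 175817 ± 82957 uninduced and 233045 ± 29162 induced (SD, n = 3). The uninduced mean includes replicate 1, whose strands were not separated, while replicates 2 and 3 held 219852 and 227472. A larger rise in poly(A)+ was also found at the snoRNA window on chromosome 3 (−3.08 ± 0.53, adjusted p = 0.0168) and opposite AT1G49245 (−3.47 ± 0.42, adjusted p = 0.00114). The overlapping window opposite ACT8, an actin gene, rose more in poly(A)+ too (−3.43 ± 0.44, adjusted p = 0.00134). Its ribo-minus signal was 30859 ± 12206 uninduced (24479 and 23165 in replicates 2 and 3) and 28736 ± 10583 induced (SD, n = 3). The AT5G53850 window, which lies within the chromosome 5 stretch, rose more in ribo-minus RNA (5.41 ± 0.77, adjusted p = 0.00325). These were the 6 strands limma called of 3600, 1 larger in ribo-minus and 5, from 3 loci, larger in poly(A)+, with 112 at an unadjusted p under 0.05. The count was 41, with 32 larger in ribo-minus and 9 in poly(A)+, without uninduced ribo-minus replicate 1. It was 3 without uninduced poly(A)+ replicate 3, induced poly(A)+ replicate 3, uninduced ribo-minus replicate 2, or any of the 3 induced ribo-minus replicates. It was 17 with the common floor and no unstranded library, where the differences were −3.82 at U2.6, −1.95 at the snoRNA window, −2.27 opposite AT1G49245 and −2.22 opposite ACT8. With the replicate number as a block, which pairs the fractions, the snoRNA window missed the threshold (adjusted p = 0.0604). When 1 library was left out, the U2.6 windows kept their call only without uninduced poly(A)+ replicate 2, induced poly(A)+ replicate 1 or 2, or uninduced ribo-minus replicate 1. The snoRNA window kept it only without uninduced poly(A)+ replicate 1 or 2, induced poly(A)+ replicate 2, or uninduced ribo-minus replicate 1 or 3.

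**Figure D2:**
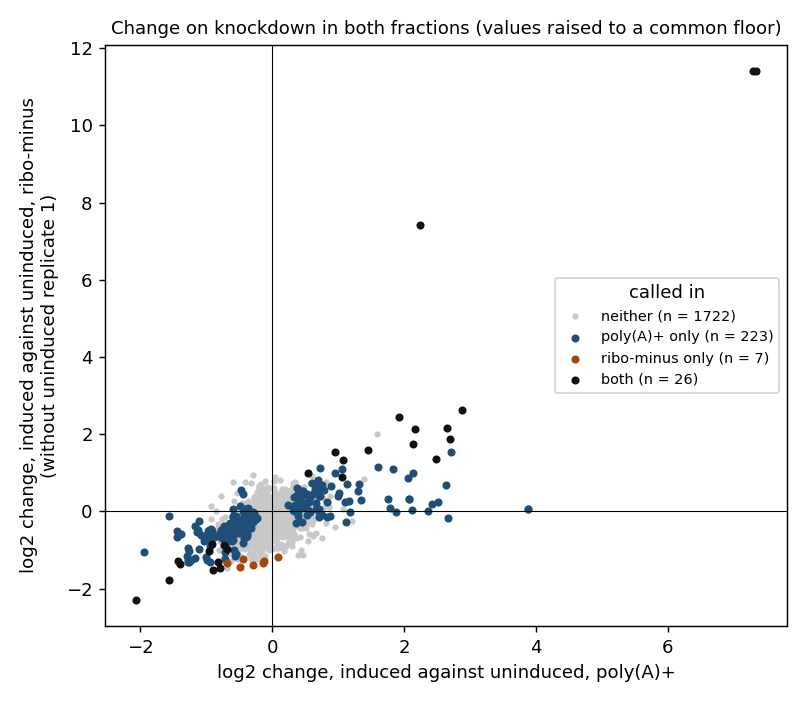
Change after knockdown (log2, values raised to the common floor) of each PE strand in poly(A)+ (horizontal axis) and ribo-minus libraries without uninduced replicate 1 (vertical axis), each point 1 strand of a window. Of 103 strands called up in poly(A)+, 87 were also higher in ribo-minus, and of 146 called down, 138 were also lower, where 29.3% of all strands drawn were higher in ribo-minus and the rest not.

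Most PE windows gave less signal in ribo-minus than in poly(A)+ libraries, with U2 windows at the other end. In induced seedlings U2.6 was 10.9-fold higher in ribo-minus than in poly(A)+ libraries (log2 3.44 ± 0.41 SE) and U2.3 8.84-fold higher (3.14 ± 0.45). AT5G24350, a gene related to neuroblastoma-amplified sequence (chromosome 5, 8302808 to 8305807, plus strand), held 7642 ± 494 in ribo-minus and 801 ± 32.5 in poly(A)+ libraries (SD, n = 3; log2 3.25 ± 0.42). The AT5G53850 window, within the chromosome 5 stretch, was higher by 3.45 ± 0.55. All 4 had an adjusted p of 9.07e-05 or below. At the other end, the strands listed at 0 in all 3 induced ribo-minus libraries held little in poly(A)+. They held 815 ± 596 at chromosome 1, 1592424 to 1595423, and 638 ± 315 at chromosome 2, 14817347 to 14820346. At the lncRNA gene AT2G08255, opposite NCRK, it was 423 ± 170, and on the strand opposite an intron of BAS 282 ± 146. AT1G29870, described above, was lower too (adjusted p = 0.0424). With the replicate number as a block, AT2G08255, the strand opposite BAS and AT1G29870 missed the threshold (adjusted p = 0.0597, 0.0742 and 0.0760). All 5 lower strands missed it with median-ratio scaling, without any 1 of the induced poly(A)+ libraries and without induced ribo-minus replicate 2, and 4 of the 5 without induced ribo-minus replicate 1 or 3. None of these 5 could be tested above the floor.

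In uninduced seedlings the strands with the largest fraction differences were listed at 0 in one fraction and held between 505 and 2884 on average in the other. Listed at 0 in poly(A)+ were a strand at chromosome 2, 14808766 to 14811765 (2228 ± 1662 in ribo-minus, SD, n = 3), and overlapping windows opposite AT2G05760 (1713 ± 903 and 1694 ± 922). So were the zinc finger gene AT1G49900 (1388 ± 627) and the lncRNA gene AT5G04345 (1366 ± 588). These ribo-minus means include replicate 1, whose strands were not separated. Replicates 2 and 3 held 1508 and 1048 at the chromosome 2 strand and 1257 and 2753 at both windows opposite AT2G05760. At AT1G49900 and AT5G04345 they held 1005 and 1048. The smallest values above 0 of these replicates were 1005 and 786, so the last values lie near a coverage of about 1 read. Listed at 0 in ribo-minus were a strand at chromosome 1, 26550752 to 26553751 (2884 ± 671 in poly(A)+), overlapping windows at AT1G09495 (1326 ± 492), the kelch-repeat gene AT5G03000 (518 ± 41.0) and the transporter gene ABCA10 (505 ± 120). Their adjusted p lay between 0.000653 and 0.0191. Raised to the common floor, the chromosome 1 strand (adjusted p = 5.31e-05) and the chromosome 2 strand at 14808766 (0.0496) kept their calls. With the floor and no unstranded library the chromosome 1 strand (1.07e-05) and the windows opposite AT2G05760 (0.00591 each) did, while the strand at 14808766 did not (0.0999). AT5G03000 and ABCA10 missed the threshold without any 1 of the uninduced poly(A)+ libraries.

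limma called 1539 of 3600 strands between fractions in uninduced seedlings, 46 higher and 1493 lower in ribo-minus, with a median change of −1.50 (log2). In induced seedlings it called 1516, 28 higher and 1488 lower, with a median of −1.34. Median-ratio scaling moved these medians to 0.03 and 0.04 and the calls to 452 higher and 497 lower uninduced, and 256 and 256 induced, so the direction for most strands rests on the deposited scale. U2.6, U2.3, AT5G24350 and the AT5G53850 window stand above either median. The AT5G53850 window lies within the chromosome 5 stretch, so its induced value is not that of the gene alone. Induced ribo-minus means were 2791060 there and 2774490 and 2774570 at the windows beside it. Uninduced, it held on average 16188 in ribo-minus replicates 2 and 3 and 52990 in poly(A)+.

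Signal on the strand opposite the annotated gene, in the 1124 windows with genes on 1 strand only, was a small share of the total except in induced ribo-minus libraries. It was 1.58 ± 0.183% (SD, n = 3) in uninduced and 3.19 ± 0.848% (n = 3) in induced poly(A)+ libraries, and 3.41 ± 0.164% (n = 2) in uninduced and 20.2 ± 2.68% (n = 3) in induced ribo-minus libraries. Without the 3 chromosome 5 windows the shares were 1.58 ± 0.183%, 2.19 ± 0.124%, 3.42 ± 0.158% and 3.71 ± 0.483%, in the same order. Two-sided exact permutation p was 0.1 for the knockdown in poly(A)+ and 0.2 in ribo-minus, 0.2 between fractions uninduced and 0.1 induced (all 0.2 after adjustment over 4 comparisons), the smallest these group sizes allow. With the gene at the midpoint as reference the poly(A)+ shares were 22.8% and 22.6%, a difference in the other direction.

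**Figure D3:**
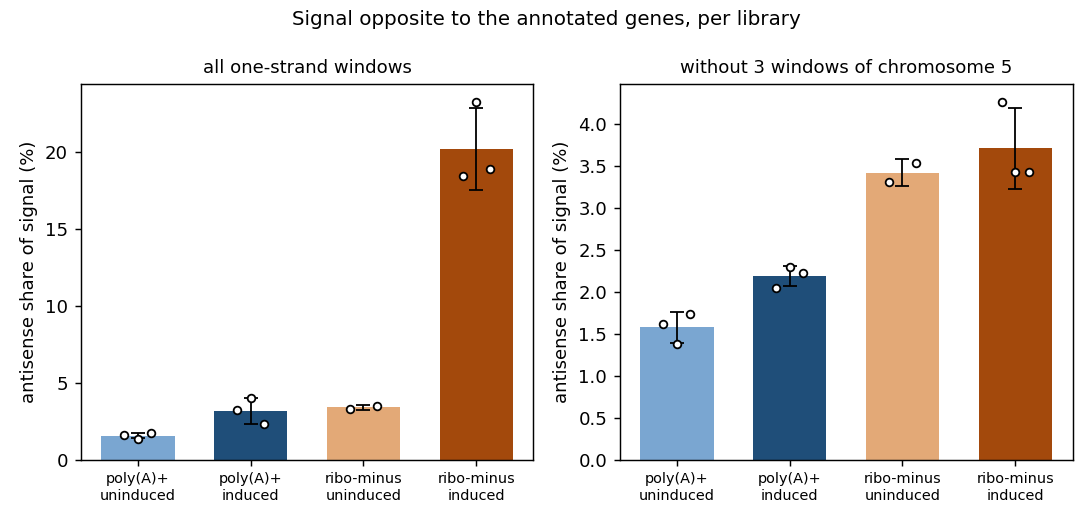
Share of PE signal (%) on the strand opposite the annotated gene in each library (points), with group means and SD (error bars); the panels show all windows and, on another scale, all but 3 chromosome 5 windows. The induced ribo-minus mean is 20.2% with these windows and 3.71% without them.

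Opposite strands more often rose than fell among the poly(A)+ calls. As designed, 9 of 753 opposite strands rose and 0 fell by limma, and 27 of 1095 gene strands rose and 26 fell, which gave rising shares of 1.195% and 2.47% (two-sided Fisher's exact p = 0.0595). With median-ratio scaling 10 opposite strands rose and 0 fell by limma, where 686 of all strands had an unadjusted p under 0.05, and 34 gene strands rose and 16 fell, so that gene strands rose more often (Fisher's exact p = 0.0131). With the replicate block 6 and 11 rose (Fisher's exact p = 0.806), and with the stricter filter 39 of 994 and 32 of 1114 (Fisher's exact p = 0.186). Of the strands above the common floor, 12 of 90 opposite strands rose and 1 fell, against 42 and 61 of 953 gene strands; the shares are not compared there, since the floor removes low strands unless their signal is high in at least 3 libraries. Strands with no gene, nearly the same windows, had a median change of 0.40 (log2), and opposite strands above the common floor 0.23. By camera the strands with no gene were higher (adjusted p = 1.75e-05, and 0.106 with an estimated correlation). Detection limits differed: 181 and 216 in induced replicates 2 and 3, 450 in induced replicate 1 and 228 to 353 in the uninduced libraries. Strands at 0 numbered 470, 461, 823 and 712 to 807, in that order. The size of this rise therefore depends on depth, and a strand at 0 in all uninduced libraries could only rise. In ribo-minus libraries 1 of 705 opposite strands and 1 of 1081 gene strands rose by limma and 0 of either fell (Fisher's exact p = 1), among the 172 at an unadjusted p under 0.05, while with the stricter filter 2 opposite strands rose and 8 fell. With the floor and no unstranded library 3 opposite strands rose and 0 fell by limma (357 of all strands at an unadjusted p under 0.05), and 4 gene strands rose and 10 fell. PEs with signal on both strands numbered 1213 ± 44.0 (SD, n = 3) uninduced and 1376 ± 189 (n = 3) induced in poly(A)+ libraries. In ribo-minus libraries they numbered 724.5 ± 111 (n = 2) and 1248 ± 316 (n = 3). The exact permutation p was 0.4 and 0.2 for the knockdown and 0.2 and 0.5 between fractions (adjusted 0.5, 0.4, 0.4 and 0.5), and with the common floor the ribo-minus means were 609 and 443, the other way round.

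Few genes of the lists fixed in advance lie at a PE midpoint. The auxin list placed 3 of 15 genes there (ARF19, TIR1 and ARF8), the exosome list 2 of 15 (RRP44A, AT2G17510, and CER7), and light signalling (PHYB, 1 of 8), the clock (LHY, 1 of 13) and flowering (SVP, 1 of 9) 1 each. Light harvesting and Rubisco, cold and dehydration, root cell types, stomatal lineage, phloem and shoot meristem placed 0. None of the auxin strands was called in poly(A)+ RNA (0 of 5; 1 when adjusted over the list alone, the TIR1 strand, which went from 58399 ± 241 to 48183 ± 1955, SD, n = 3, log2 change −0.28 ± 0.06 SE, adjusted p = 0.0511 by limma over all strands). Signal on the gene strand of the exosome nuclease RRP44A was 13976 ± 1152 uninduced and 13972 ± 1296 induced, and at CER7 it was 12842 ± 883 and 13952 ± 1088. PHYB, LHY and SVP strands were not called either.

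By function of the midpoint gene, poly(A)+ calls were few in every list. Each list holds both strands of its windows, so strands opposite the listed gene are included and a result for a list is not one for its genes alone. Of protein kinase strands 5 rose and 2 fell of 152 (9 adjusted over the list alone), of transporters 3 and 1 of 64 (7), of ubiquitin and proteasome genes 1 and 2 of 55 (6), and of transcription factors 3 and 0 of 29 (4). Of heat shock and chaperone strands 2 rose of 29 (2 over the list alone), of RNA-binding and splicing genes 2 of 26 (5), and of chloroplast and photosynthesis genes 1 fell of 14 (1). Camera called none of the 10 lists in either fraction, with the preset or an estimated correlation (lowest adjusted p 0.163 in poly(A)+ and 0.624 in ribo-minus). By fry, the chloroplast (adjusted p = 0.00049) and auxin (0.0486) lists were lower and the chaperone list (0.0176) higher in poly(A)+. No list passed fry in ribo-minus. With the common floor the chloroplast list no longer passed fry (adjusted p = 0.253), while the auxin and chaperone lists did (0.0437 each). With the block the auxin list did not pass fry (adjusted p = 0.0575), while the RNA-binding and splicing list then passed as higher (0.0174). Nor did camera or fry call any of 7 classes of window by position: intron, coding exon, 5' UTR, 3' UTR, start of the host gene in the window, noncoding gene and outside genes (lowest camera adjusted p 0.875 in poly(A)+ and 0.958 in ribo-minus). In ribo-minus libraries, the ubiquitin list held 1 call of 52, and the other lists 0. That call is the U1.7 window described above, whose midpoint lies in AT3G05670, a RING/U-box gene, so it is no separate response.

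Of the 9 sets by gene type on the strand, chosen after the values were seen, 4 passed camera in poly(A)+ RNA. These were snRNA or snoRNA genes, strands with no gene, strands opposite a gene, and lncRNA genes alone on their strand (1 of 70 up, adjusted p = 0.00116). With an estimated correlation none of the 4 passed (adjusted p = 0.414, 0.106, 0.106 and 0.252, in that order). The sets not called were tRNA genes (0 up and 1 down of 65, adjusted p = 0.194), small RNA genes of any kind (7 and 2 of 78, 0.977) and all lncRNA genes (3 and 2 of 154, 0.516). MicroRNA genes (0 and 0 of 10, 0.339) and gene strands (27 and 26 of 1095, 0.0594) were not called either. In ribo-minus libraries as designed camera called none of the 9 (lowest adjusted p 0.06).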

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

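All tests of explanations in this part were chosen after the results were seen; the interaction fit itself was planned.

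The change after knockdown differed between poly(A)+ and ribo-minus RNA at 6 strands by the interaction term of limma. The difference of log2 changes (ribo-minus minus poly(A)+) was 5.41 at the AT5G53850 window, which lies within the chromosome 5 stretch. It was −3.47 opposite AT1G49245, −3.43 opposite ACT8, −3.33 in each of the overlapping U2.6 windows and −3.08 at the snoRNA window on chromosome 3. Of 100 drawn regroupings of the libraries within each fraction, 10 gave 6 or more calls, the real one included, and the highest other gave 34, so chance is not excluded for a count of 6. Most of these regroupings part libraries made from the same total RNA. The 10 splits that keep such pairs together are too few for a share under 0.05, with 6 calls in the real split and 0 in the highest other.

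The stretch on the minus strand of chromosome 5 held far more signal in induced than in uninduced libraries. The outer windows, which start 46565 bp apart, differed by 0% to 2.15% in the 6 induced libraries. Both held 2546540 in induced ribo-minus replicate 1. Of 651 other neighbouring pairs of windows, 0 lay within 5% in all of these libraries. This fits 1 even stretch of coverage over the windows rather than separate PE transcripts. Whether the stretch is continuous RNA or comes from how reads were placed and values made was not tested. Depth is argued against, since the lowest induced value was 27.9 times the smallest value above 0 of the shallowest library. RNA of the induced construct, such as transcription out of its insertion site, is a candidate explanation: all 6 induced libraries held the signal. It cannot be told apart from an effect of the knockdown, because the design puts construct induction and knockdown in the same libraries.

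For the rise of snRNA and snoRNA windows in poly(A)+ RNA, 8 such windows were called up with a common floor against 7 as designed. Both counts include the overlapping U2.6 windows. Rises over all strands went from 78 to 110 with the floor too, so the count does not decide on depth. With the floor, which every library could show, the log2 changes of the called windows were 0.95 (U1.7) to 3.87 (U2.6). This argues against differing detection limits as the only source of their rise. Carry-over of RNA without a tail into induced poly(A)+ libraries was assumed to add an equal percent of ribo-minus signal at every window of such RNA. This assumption was not tested, and the signal is not an amount of RNA. Carry-over that differs between RNAs was not examined. At the U2 windows the gain was 9.28% to 12.8%. At other windows enriched in ribo-minus it had a median of 0.314% (interquartile range −10.1% to 13.9%), and in the 30 most enriched 1.23% (upper quartile 8.87%). These windows do not decide, since their median enrichment (log2 0.82, and 1.67 in the 30) lay below that of the small RNA windows (5.05). The tested ones nearest to it, opposite AT1G49245 and ACT8 (4.69 and 4.57), rose in poly(A)+ from 524 to 5808 and from 541 to 5462. The next, over CNGC10 and PPC3 (3.48 and 3.14), went from 2978 to 3378 and from 2264 to 1854. In this order, their induced ribo-minus means were 32299, 28736, 26755 and 7039. The U2 libraries allow gains from 2.42% (U2.10b/12) or 5.16% (the other U2 windows), so carry-over stays open there. At the snoRNA window on chromosome 3 the lowest gain its libraries allow was 72.1%. The U2 windows allow at most 28.2% (U2.10b/12) or 17.6% (the others). This argues against carry-over at an equal percent as the source there, and only under that assumption. At the snoRNA window on chromosome 5 the lowest gain was 23.0%, within what U2.10b/12 allows but above the other U2 windows, so carry-over stays open. The chromosome 5 window also rose in ribo-minus RNA with the floor and no unstranded library (limma log2 change 1.60, adjusted p = 0.0154). An effect of the knockdown itself stays open and untested.

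Of the 10 splits of the 6 ribo-minus libraries, 2 gave as many calls as the real one (5), itself included, and the highest other gave 258, which points to a structure of the samples other than induction. That split set uninduced replicate 1 and induced replicates 2 and 3, the deepest 3, against the rest. With the common floor it gave 0 calls by limma (247 strands at unadjusted p under 0.05), and without the library whose strands were not separated it gave 0 as well (474 at unadjusted p under 0.05); 253 of the 258 strands were at 0 in all 3 shallower libraries. Both depth and that library may contribute, and no biological explanation of this split was tested.

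For the other comparisons the splits are too few for a share under 0.05. In poly(A)+ RNA the real split gave 136 calls and the highest other 0 (1 of 10 splits as large), and with the common floor 262 against 1 (1 of 10). Between fractions the real split gave 1539 against 1 uninduced (1 of 10) and 1516 against 0 induced (1 of 10), and the same among the 4 splits that part every pair from the same total RNA.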

How the results depend on the processing

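The common floor, its combinations, the midpoint host, the shares without the 3 chromosome 5 windows and the values with or without the unstranded library were tried after the data were seen; the other alternatives were planned. Of the main results, 169 values under alternatives kept direction and their side of the threshold (counts within 1.5 times), 39 moved and 7 reversed; of those for named strands, 689 stayed, 127 lost and 13 gained the call, and 6 reversed. A kept direction does not mean a kept size. Without the 10 highest PEs by mean over all libraries, the ribo-minus knockdown difference in opposite-strand share was 0.317 in place of 16.8. Depth limits values under 1005, and where no cause is given, the cause was not tested.

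For the knockdown in poly(A)+ RNA (136 calls) there were 229 with no filter and with the stricter filter, 17 with all 12 libraries, 262 with the common floor and 246 with the floor and the block. Leaving out 1 library gave 68 to 202 (68 without uninduced replicate 2, 69 without uninduced replicate 3, 84 and 85 without induced replicates 1 and 2). For ribo-minus (5) there were 40 (11 up, 29 down) with no filter and with the stricter filter, 2 with scaling, 8 without the trend, 10 with summed strands, 12 with all 12 libraries and 33 with the floor and no unstranded library. Of the 5 calls as designed, 4 were lost with scaling, 4 without the trend, 1 with summed strands and 1 with all 12 libraries. Leaving out 1 gave 3 to 61 (10, 61 and 59 without uninduced replicates 1, 2 and 3, the last 2 mostly falls, 3 and 12 without induced replicates 1 and 3). For the interaction (6) there were 10 without the trend (6 larger in ribo-minus, 4 in poly(A)+), 5 with scaling and 17 with the floor and no unstranded library. Of the 6 strands, 2 lost their call without the trend and 2 with scaling. Leaving out 1 gave 3 to 41, with 41 without uninduced ribo-minus replicate 1 (32 larger in ribo-minus). It gave 3 without uninduced poly(A)+ replicate 3, induced poly(A)+ replicate 3, uninduced ribo-minus replicate 2 or any induced ribo-minus replicate. Between fractions, scaling gave 949 uninduced (1539) and 512 induced (1516), and leaving out 1 gave 1425 to 1787 and 1364 to 1529.

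Replicate numbers do not pair knockdown and control (same-number correlations −0.14 to 0.08 in poly(A)+ and −0.03 to 0.05 in ribo-minus, over 1375 windows). Across fractions, which share total RNA, they were 0.20 to 0.28 uninduced and 0.11 to 0.36 induced. With the replicate number as a block there were 64 calls in poly(A)+, 10 in ribo-minus, 5 for the interaction, and 1559 and 1512 between fractions.

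Opposite strands that rose numbered 39 in poly(A)+ with the stricter filter (9), where 6 fell; in ribo-minus (1) they numbered 2 with the stricter filter, where 8 fell, 0 with scaling (302 strands at an unadjusted p under 0.05 by limma), 2 with the floor and 3 with the floor and no unstranded library. With strands summed, which adds the gene strand, these reversed: the strand opposite AT1G49245 in poly(A)+ (−0.055) and in the interaction (0.25), the interaction opposite ACT8 (0.23) and at the chromosome 3 snoRNA window (0.073), and between fractions uninduced the strand at chromosome 2, 14808766 (−0.45), and AT1G49900 (−1.99).

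With the common floor the knockdown difference in detected PEs in ribo-minus became −39.7 and in PEs with both strands −165.667 (ribo-minus), and the fraction difference in the latter, uninduced, 151. Between fractions in induced seedlings, leaving out 1 library gave −33.3 to 10.2 for detected PEs and −244.5 to 51.5 for both strands, the sign turning without induced ribo-minus replicate 1. The opposite-strand share reversed for the knockdown in poly(A)+ with the midpoint host (−0.209) and between fractions uninduced with the median over PEs (−0.660). With the unstranded library the differences in both-strand PEs were 152.667 for the ribo-minus knockdown and −118.333 between fractions uninduced, and those in opposite-strand share 1.29 and 17.4. No other range crossed 0 on leaving out 1 library.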

Other observations

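The strands described here were chosen after their values were seen, as were the common floor and the count of shared calls.

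Without the floor, and without the unstranded library in ribo-minus, 7 strands were called after knockdown in both fractions, 6 up and 1 down. With the common floor, and again without that library, there were 26 such strands, 15 up and 11 down, each with the same sign in both. Among those up was the minus strand at chromosome 1, 29802832 to 29805831, over AT1G79245, which went from 157647 ± 19587 to 702755 ± 62409 in poly(A)+ (SD, n = 3; log2 change 2.16 ± 0.11 SE, adjusted p = 2.16e-05) and from 36966 (n = 2) to 161167 ± 25928 in ribo-minus (2.13 ± 0.18, adjusted p = 0.000129). AT1G03495, of an acyltransferase family, rose by 2.70 and 1.88 (log2, poly(A)+ and ribo-minus), BPC7, a transcription factor gene of the basic pentacysteine family, by 2.48 and 1.37, and BGLU11, a beta-glucosidase gene, by 1.08 and 1.34. AT5G27120, for a NOP56-like protein of the kind bound to box C/D snoRNAs, rose by 0.54 and 1.00. On strands without a gene, the one opposite AT3G43610 rose by 2.66 and 2.16, and the minus strand at chromosome 3, 15189170 to 15192169, by 1.92 and 2.45.

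Among those down were DWF1 and CPD, both enzymes of brassinosteroid synthesis. DWF1 went from 106758 ± 1763 to 65317 ± 14619 in poly(A)+ (log2 change −0.73 ± 0.13, adjusted p = 0.00832) and from 100212 to 55495 ± 10272 in ribo-minus (−0.87 ± 0.17, adjusted p = 0.0379). CPD went from 142742 ± 16223 to 73449 ± 4251 (−0.95 ± 0.09, adjusted p = 0.000402) and from 49090 to 24291 ± 1313 (−1.01 ± 0.14, adjusted p = 0.00571). Log2 changes in poly(A)+ and ribo-minus were −0.68 and −0.97 at DFL1, a gene of the auxin-responsive GH3 family, −0.89 and −1.52 at SBT4.12, a subtilase gene, and −2.06 and −2.29 at AT3G58550. Both fractions came from the same total RNA, so the second is no independent replicate of the first. Over 1978 strands tested in both, which are not independent replicates either, changes correlated with Pearson's r = 0.674 (0.562 without the chromosome 5 windows) and Spearman's rho = 0.501.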
